A study of Mus musculus with 4 samples.

How the data were processed

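RNA from cultured B16-F10 cells, a mouse melanoma line, was measured in 4 libraries. Per the labels' protocols, fluorescent cells had been infused into zebrafish, recovered and grown in IMDM with serum, total RNA was purified with a miRNeasy kit, and polyA libraries were made with a stranded TruSeq mRNA kit. The groups were taken from the labels' extravasation field: 2 libraries were marked as having extravasated and 2 as not. The growth text in the labels describes extravasated cells for all 4 libraries, and the group rests on the extravasation field and the source name. The sample titles carry 1 number for all extravasated libraries and another for all others, so whatever that number stands for cannot be told apart from the group. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicate numbers only name the libraries.

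The deposited values were raw read counts per gene, whole numbers with no normalization. STAR 2.5.3a, bcl2fastq 2.18.0.12 and the GRCm38 build are named per the submitters' processing notes. The counter, the annotation release, the strand setting and any filter were not given in the sources used here. Reads of overlapping, antisense or near-identical genes may therefore have been split or dropped by the counting, and values of such genes are uncertain. The table held 53465 genes, of which 32416 had no read in any library. Of the identifiers, 50604 matched the GENCODE M21 annotation (GRCm38) with their version, 53360 matched without it, and 105 did not match. Library totals were 11705904 and 16430477 counts in the non-extravasated libraries and 13256522 and 19674733 in the extravasated libraries.

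Differential expression was tested with edgeR 4.0.16 (R 4.3.3): the default expression filter (minimum count 10, minimum total 15), TMM factors, robust dispersion, and the two-sided quasi-likelihood test of extravasated against not extravasated libraries without covariates. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. Standard errors were derived from the fold change and the F statistic. Levels are TMM-scaled CPM (counts scaled to a common library total). Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested members; camera with an estimated correlation and fry were run beside it. With all libraries, that correlation is estimated from only 2 residual degrees of freedom. With 1 library left out, or with the title suffix term, it is estimated from 1. With all libraries and no correction, the 28 tested lists shared 1 adjusted p of 0.866 with an estimated correlation, so that value does not tell the lists apart. The 34 lists and the tests were fixed before the data were examined, as was the rule for named genes. That rule took the 12 highest and 12 lowest fold changes among called genes with a mean of at least 10 CPM and non-overlapping groups, without predicted and ribosomal protein genes. It added up to 4 called members per list with the smallest adjusted p, 6 pigment cell genes and 10 adhesion and invasion genes whether or not called. It yielded 139 tested genes, of which a part is described. Some items are not reported here.

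A trend of fold changes with transcript GC content was seen in the data, and a correction was then added. For each library, the deviation of each gene's log2 CPM from the mean of the 4 libraries was smoothed against GC content and log2 length of the gene's transcript (mgcv 1.9.3, basis size 10) and entered edgeR as an offset. Mitochondrially encoded genes were left out of the smooth and received no correction. The transcript was the coding one tagged as APPRIS principal, with support level and length deciding ties. The longest coding transcript had been used first, and the choice was changed after corrected results had been seen; the numbers of changed genes and called lists are given for both, as are the described genes whose call differs. The annotated transcript need not be the one these cells express. Transcript properties were known for 99.89% of tested genes.

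The alternatives fixed beforehand were RLE and upper quartile factors, DESeq2 1.42.0, limma-voom, no expression filter, a filter of CPM above 1 in at least 2 libraries, no robust moderation, the kind of title suffix as an additive term, a test against a fold of 1.5, an adjusted p under 0.01, and leaving out each library. Alternatives added after seeing the data were the GC and length correction, with either transcript choice and with each library left out, GC correction alone, library totals without scaling, and camera with an estimated correlation under the alternatives that called further lists.

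The code was tested on simulated counts with the means, library sizes and trended dispersions of the 12320 tested genes, in 5 simulations of this comparison with 200 changed genes each. Without a trend, 17.1% of genes changed 1.5-fold, 61.3% of those changed 2-fold and 93.3% of those changed 4-fold were recovered, and 4.23% of calls were false. With the smoothed GC and length trend of the real libraries added, 96.9% of calls of the uncorrected test were false. After correction this was 4.13%, with 19.9%, 68.8% and 93.9% recovered at the 3 fold sizes. That simulation used the trend model that the correction removes, so it tests the code and not the form of the real trend. A list of 30 genes shifted 1.5-fold, tested alone, had an unadjusted camera p under 0.05 in 5 of 5 simulations with either correlation. Its genes were drawn from those with higher mean counts. Whether it would pass the adjustment over all lists used for the real data was not tested. The simulated genes varied independently of each other. This therefore does not show whether camera with an estimated correlation can call a real list whose members vary together.

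Count data at these depths limit genes of few counts; Wilson intervals cover counting error only, and bootstrap intervals cover the spread across genes, which are not independent replicates. No library pair agreed within sampling noise: the chi-square per degree of freedom was 27.8 between the non-extravasated and 16.2 between the extravasated libraries, and at least 99.9 between groups. Figures were drawn with matplotlib from the result tables.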

Results

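The data compared B16-F10 mouse melanoma cells that had left the vessels of zebrafish with cells that had been infused and had not, all measured by polyA RNA sequencing after culture. The series' design text names the cells that did not extravasate as the control. Each group held 2 libraries. Total counts were 11705904 and 16430477 in not_extravasated_1 and not_extravasated_2, and 13256522 and 19674733 in extravasated_1 and extravasated_2. Mitochondrially encoded genes took 8.21% of counts (95% Wilson interval 8.19 to 8.22), 7.12% (7.11 to 7.13), 6.51% (6.5 to 6.53) and 8.88% (8.87 to 8.90) in the same order. Pearson correlations of log2 CPM were 0.979 within the non-extravasated and 0.989 within the extravasated group, and 0.934 to 0.945 between groups. These are correlations across genes, which are not independent replicates.

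The comparison asked which transcripts differed between cells that had extravasated and cells that had not. The called gene with the largest rise under the naming rule was Id3, an inhibitor of basic helix-loop-helix transcription factors (ENSMUSG00000007872.3, GRCm38 chromosome 4, 136143497 to 136145755). It stood at 31.9 ± 1.37 CPM (SD, n = 2) in extravasated and 8.43 ± 3.17 CPM (SD, n = 2) in non-extravasated libraries, a log2 fold change of 1.94 ± 0.265 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00197). Esrra, an orphan nuclear receptor, rose 2.61-fold, and Lypla2, a thioesterase, rose 2.69-fold. Under the naming rule, which asks for a mean of at least 10 CPM, the largest falls were in Nfat5, the transcription factor of the osmotic stress response (chromosome 8, 107293470 to 107379517), and in Malat1, an abundant nuclear long non-coding RNA (chromosome 19, 5795690 to 5802672). Nfat5 fell 8.18-fold, from 74.3 ± 29.9 to 9.06 ± 0.148 CPM (SD, n = 2 each), and Malat1 fell 8.16-fold, from 354.8 ± 6.73 to 43.5 ± 9.39 CPM (SD, n = 2 each). Ahnak, Tet2 and Mdm4, a p53 inhibitor, fell 6.77-, 6.96- and 6.47-fold. After GC and length correction, Id3 (log2 fold change 1.41), Esrra (0.87), Lypla2 (0.85), Nfat5 (-2.63), Malat1 (-1.74), Ahnak (-3.42), Tet2 (-1.71) and Mdm4 (-1.47) kept their call. The corrected values of Ahnak and Nfat5 depend on the transcript used, of 830 and 4982 nucleotides. With the longest annotated transcripts, of 18100 and 13380 nucleotides, they were -1.66 and -1.37, and both were called. Bnip3, a hypoxia-induced mitophagy gene, was also among the largest falls under that rule with a log2 fold change of -3.00, but its levels in the non-extravasated libraries were 33.3 and 127.9 CPM and its call ended after correction, with a log2 fold change of -2.10 (adjusted p = 0.201). Without not_extravasated_2 its log2 fold change was -1.72, and without extravasated_1 or extravasated_2 it was -3.08 and -2.95 and not called (adjusted p = 0.0882 and 0.128).

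Of 12320 genes tested with edgeR, 5551 (45.1%) differed, 2355 higher and 3196 lower in extravasated cells. At 2-fold or more, 216 were higher and 2101 lower. These counts moved with the GC content of the transcripts. Among 11126 nuclear coding genes, the fold change had a Spearman rho of 0.745 with transcript GC content and -0.379 with transcript length, and both together accounted for 59.2% of its variance across genes, which are not independent replicates. Among the 1113 genes with the lowest GC content (33.4 to 42.0%), 870 fell and 1 rose, with a median log2 fold change of -1.27. Among the 1113 with the highest, 533 rose and 2 fell, with a median of 0.53. Between libraries of 1 group, rho with GC was -0.26 for not_extravasated_1 minus not_extravasated_2 and -0.23 for extravasated_1 minus extravasated_2. With the GC and length correction, added after the trend was seen, 1705 genes differed, 1005 higher and 700 lower. Of these, 415 higher and 628 lower genes had the same call without correction, 604 were called only after it, and 58 turned direction. Across nuclear coding genes, the correction brought rho to 0.01 with transcript GC content and -0.02 with transcript length. With coding sequence length, rho was -0.24 before and -0.19 after correction. With the length and GC content of the untranslated region behind the coding sequence, rho was 0.13 and 0.12 after correction. Trends with transcript properties thus stayed in part. Without extravasated_1 or extravasated_2 the uncorrected count was 3241 or 1677, and the corrected count was 5 or 0 (edgeR, with 2404 and 2052 genes at an unadjusted p under 0.05). Without not_extravasated_1 the corrected count was 2886. These fits assume that the lone library varies like the other group. Without an extravasated library the spread came from the non-extravasated libraries alone. Those differed more from each other (chi-square per degree of freedom 27.8, against 16.2 between the extravasated libraries). A call lost there need not mean a smaller change. Of the 139 named genes, 62 lost their call without extravasated_2 and 31 without extravasated_1, among them Bnip3, Vegfa, Mitf, Tyr, Cd44, Ifit2 and Vwf without either. Gpr143, Sox10, Pold1, Rsad2, Tln1, Ncam1, Ctsa, Plvap and Hmgcs1 lost it without extravasated_2 alone. There all of these kept their direction with somewhat smaller log2 fold changes, such as Sox10 at 0.645 against 0.774 and Rsad2 at -1.12 against -1.16.

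**Figure D1:**
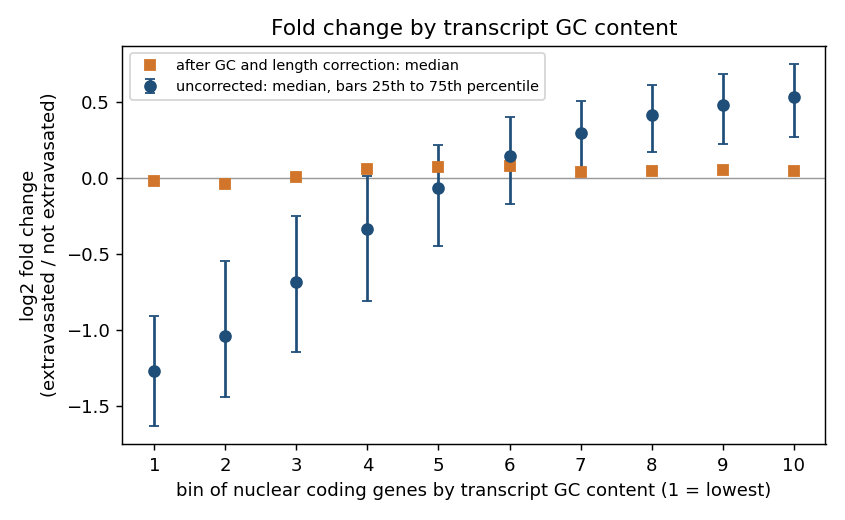
Median log2 fold change (extravasated over not extravasated) of nuclear coding genes in 10 equal bins of transcript GC content, before correction (circles, bars from the 25th to the 75th percentile of genes) and after GC and length correction (squares, median). The uncorrected median ran from -1.27 in the lowest to 0.53 in the highest bin.

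Oxidative phosphorylation genes, which encode respiratory chain and ATP synthase subunits, were higher in extravasated cells: 25 of 44 tested members rose and 2 fell (27 and 2 adjusted over the list alone). Cyc1, the cytochrome c1 subunit of complex III, rose from 137.0 ± 0.0829 to 292.6 ± 24.0 CPM (SD, n = 2 each). Atp5d, a subunit of ATP synthase, rose 2.12-fold, and Ndufb8 and Uqcrc1 had log2 fold changes of 0.90 and 0.84. The list was called by camera (adjusted p = 3.58e-05), and not with an estimated correlation (adjusted p = 0.866). After GC and length correction 17 members rose and none of the 44 fell, camera's adjusted p was 0.00011 (adjusted p = 0.80 with an estimated correlation), and Cyc1 (0.60) kept its call while Atp5d (0.38), Ndufb8 (0.28) and Uqcrc1 (0.32) did not. With the longest transcripts Atp5d (0.48) and Ndufb8 (1.26) were called. Whether the trend with coding sequence length that stayed after correction shapes the rises of this list was not tested. Without extravasated_2 only 7 members rose, although camera called the list (adjusted p = 0.000156; adjusted p = 0.92 with an estimated correlation).

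Pigmentation genes were higher as a list (camera adjusted p = 0.0237; adjusted p = 0.866 with an estimated correlation): 6 of 20 tested members rose and 2 fell, also adjusted over the list alone. Pmel, the melanosome matrix protein, rose from 4810 ± 338.5 to 8134 ± 174 CPM (SD, n = 2 each), and Bace2, a protease that processes it, rose 1.79-fold. Gpr143, a melanosomal receptor, rose with a log2 fold change of 0.81. After correction Bace2 (1.77) and Gpr143 (0.72) kept their call and Pmel did not (0.42, adjusted p = 0.057). Tyr, the rate-limiting enzyme of melanin synthesis, fell with a log2 fold change of -0.60 (adjusted p = 0.0268), and its value was 0.78 after correction (adjusted p = 0.0505). Dct had a log2 fold change of 0.26 (adjusted p = 0.136) and Mlana of 0.47 (adjusted p = 0.0654); neither passed, while both passed without not_extravasated_1 (0.41 and 0.76), and Mlana passed after correction with 0.75. After correction 7 members rose, and the list was called with a camera adjusted p of 0.00037 (0.80 with an estimated correlation). The corrected median log2 fold change was 0.58, and 0.46 to 0.64 with 1 library left out. Without not_extravasated_2 the uncorrected list was not called (median log2 fold change 0.26, against 0.47 with all libraries; adjusted p = 0.0725), and the number of members that rose was 2 without extravasated_2 and 13 without not_extravasated_1. Among regulators of the neural crest and of melanocytes, 2 of 15 rose and 6 fell, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.704). Without extravasated_1 or extravasated_2, 3 or 2 fell, and 4 rose without not_extravasated_1. Sox10, a neural crest transcription factor, rose 1.71-fold. Mitf, the melanocyte master regulator, fell 2.30-fold, from 425.2 ± 148 to 184.7 ± 25.9 CPM (SD, n = 2 each). After correction neither was called, with log2 fold changes of 0.28 and -0.11. Of the 15 regulators 2 rose and 0 fell after correction, with a list median of 0.03, against -0.20 before it.

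Genes of the G1/S phase, which act in DNA replication, were higher as a list (camera adjusted p = 0.0217; adjusted p = 0.866 with an estimated correlation), with 12 of 30 members up and 2 down, also adjusted over the list alone. Cdt1, a replication licensing factor, and Pold1, a DNA polymerase subunit, rose with log2 fold changes of 0.78 and 0.80. Slbp, which binds histone mRNA, fell with -0.96. After correction 7 rose and 1, Slbp, fell (camera adjusted p = 0.00045, and 0.80 with an estimated correlation). Cdt1 (0.29) and Pold1 (0.37) were no longer called. The corrected list median was 0.29, and 0.28 to 0.33 with 1 library left out. Without not_extravasated_1 the uncorrected list was not called (median log2 fold change 0.27, against 0.30 with all libraries; adjusted p = 0.054), and 1 member rose and 1 fell without extravasated_2, against 6 and 2 without extravasated_1. Of 30 G2/M genes 3 rose and 15 fell (3 and 16 adjusted over the list alone). Anln, an actin-binding protein of cytokinesis, fell 2.97-fold, and Kif11, a mitotic motor, fell 3.60-fold. Without extravasated_2, 8 fell and 0 rose, and without extravasated_1, 10 and 1. The median log2 fold change was -0.46. Camera did not call that list (adjusted p = 0.0542; adjusted p = 0.866 with an estimated correlation). It did without not_extravasated_1 (0.0248), without extravasated_2 (0.0398) and with the kind of title suffix as an additive term (0.0324), where the adjusted p with an estimated correlation was 0.82, 0.92 and 0.897. Fry called it (adjusted p = 0.0478) and none of the 6 lists called by camera: its adjusted p was 0.0957 for oxidative phosphorylation, 0.104 for G1/S, 0.166 for hypoxia and for lysosome, 0.168 for pigmentation and 0.222 for interferon response. After correction 1 G2/M member rose and 3 fell, Anln and Kif11 among the latter, and the list's median was -0.02 with a camera adjusted p of 0.239.

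Lysosomal genes were called higher (camera adjusted p = 0.0217; adjusted p = 0.866 with an estimated correlation), with 15 of 31 members up and 3 down (17 and 3 adjusted over the list alone). Ctsa, a lysosomal carboxypeptidase, rose with a log2 fold change of 0.62, and Lamp2, a lysosomal membrane protein, fell with -0.98. After correction 5 rose and none of the 31 fell (adjusted p = 0.035; adjusted p = 0.80 with an estimated correlation), and Ctsa (0.23) and Lamp2 (0.23) were not called. Fewer members were called without extravasated_1 or extravasated_2, where the uncorrected median was 0.45 and 0.31, against 0.38 with all libraries. The uncorrected list was called by camera without each library in turn, and not with an estimated correlation. The corrected list was not called without extravasated_2, with a median of 0.20 against 0.23 with all libraries.

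Hypoxia genes were lower in extravasated cells (camera adjusted p = 0.0217; adjusted p = 0.866 with an estimated correlation): 12 of 28 fell and 2 rose, also adjusted over the list alone. The number that fell was 5 without extravasated_1 or extravasated_2 and 21 without not_extravasated_1. Plod2, a collagen lysyl hydroxylase, fell 3.67-fold, from 182.2 ± 5.42 to 49.6 ± 0.935 CPM (SD, n = 2 each), and Kdm3a, a histone demethylase, fell with a log2 fold change of -1.34. Vegfa, the vascular growth factor, stood at 57.5 and 110.5 CPM in the non-extravasated libraries and at 36.0 and 32.5 CPM in the extravasated ones, a log2 fold change of -1.30 ± 0.318 (SE; edgeR, adjusted p = 0.0235). The Vegfa value was -0.75 without not_extravasated_2, and -1.35 and -1.27 without extravasated_1 or extravasated_2, where it was not called (adjusted p = 0.0966 and 0.14). All 3 kept their call after correction, Vegfa with -1.77 on a transcript of 654 nucleotides and -1.34 on the longest one, when 7 members fell and none of the 28 rose (adjusted p = 0.00015; adjusted p = 0.80 with an estimated correlation). The list's median deviation from the mean of the 4 libraries was 0.74 in not_extravasated_2, 0.07 in not_extravasated_1, -0.33 in extravasated_1 and -0.41 in extravasated_2. Without not_extravasated_2 the list was not called (median log2 fold change -0.30, adjusted p = 0.0865), nor without extravasated_1, where the median was -0.89 (adjusted p = 0.0722), against -0.87 with all libraries. With camera's preset correlation the corrected list was called without each library in turn. An estimated correlation was not tried in those fits. The corrected median was -0.86 with all libraries, -0.21 without not_extravasated_2, -0.98 without not_extravasated_1, -0.85 without extravasated_1 and -0.79 without extravasated_2.

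Interferon response genes were lower (camera adjusted p = 0.0279; adjusted p = 0.866 with an estimated correlation): 8 of 29 fell and 0 rose (5 and 0 adjusted over the list alone). By edgeR fewer members fell without either extravasated library, more fell without not_extravasated_2, and some rose without not_extravasated_1. The list's median was -0.68 without extravasated_2 and -0.92 without not_extravasated_2, against -0.65 with all libraries. Rsad2, an antiviral enzyme, fell with a log2 fold change of -1.16, and Ifit2 with -1.36. After correction 0 of 29 members were called by edgeR, with Rsad2 at -0.26 and Ifit2 at -0.23, while the list's camera adjusted p was 0.00072 (0.80 with an estimated correlation). Its median deviation was 0.59 in not_extravasated_1 and -0.16 in not_extravasated_2, against -0.30 and -0.29 in the extravasated libraries. Without not_extravasated_1 it was not called (median log2 fold change -0.33, adjusted p = 0.492), nor without extravasated_1, where the median was -0.69 (adjusted p = 0.0818), against -0.65 with all libraries. The corrected list was not called without not_extravasated_1 either, with a median of -0.02 (adjusted p = 0.454).

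**Figure D2:**
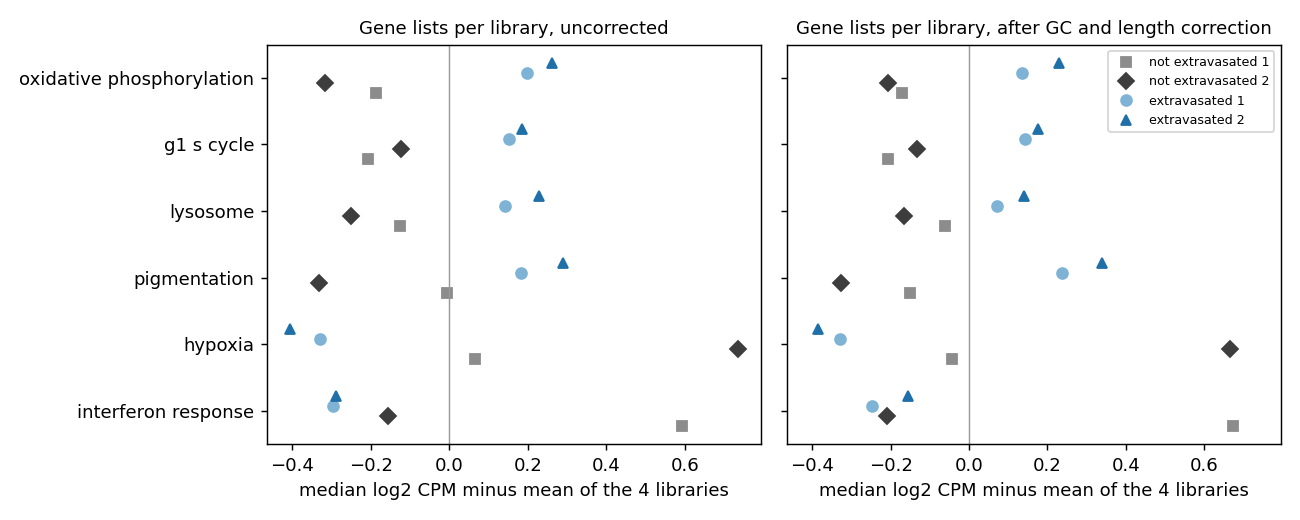
Median log2 CPM of the members of the 6 called lists, as the difference from the mean of the 4 libraries, in each library (squares and diamonds, not extravasated; circles and triangles, extravasated), before and after GC and length correction. Hypoxia stood at 0.74 in not_extravasated_2 and interferon response at 0.59 in not_extravasated_1, away from the other non-extravasated library in each case.

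Genes of adhesion and invasion chosen beforehand differed as follows. Itgb1, the beta-1 integrin, fell 2.19-fold, from 785.0 ± 83.9 to 357.8 ± 34.5 CPM (SD, n = 2 each), and Cd44, a hyaluronan receptor, fell 1.72-fold. After correction neither was called, with log2 fold changes of -0.34 and 0.20. Cdh1 (0.79), Cdh2 (-0.27), Vim (0.30), Fn1 (-0.28), Itgb3 (0.25) and Mcam (1.12) did not pass in log2 fold change; Mcam stood at 212.6 and 59.7 CPM in the non-extravasated libraries and passed without either of them (2.31 without not_extravasated_1, 0.47 without not_extravasated_2), and Vim passed without not_extravasated_1 (0.42). Mmp9 had 0, 1, 0 and 3 counts and was not tested. Of 16 integrins 1 rose and 6 fell, among them Itgav (-1.67) and Itga6 (-1.23). Fewer fell without extravasated_1, where the list median was -0.46, against -0.33 with all libraries. After correction 0 integrins rose and 1 fell, Itga6 (-0.95). Of 28 cell-cell adhesion genes 9 fell and 0 rose, among them the adhesion molecules Ncam1 (-1.0) and Cadm1 (-1.07). After correction 2 rose and 1 fell, and neither Ncam1 (adjusted p = 0.0657) nor Cadm1 (adjusted p = 0.565) was called. With the longest transcripts Itgav and Ncam1 were called (-0.48 and -0.70). Without extravasated_2 only 1 cell-cell adhesion gene fell, and without extravasated_1 only 4. Of 4 epithelial junction genes, too few for a list test, 1 fell: Tjp1, a tight junction scaffold, with -1.66, and -0.89 after correction. Of 35 motility and actin genes 7 rose and 7 fell, and 5 rose and 1 fell after correction. Tln1, which links integrins to actin, rose 1.55-fold and kept its call after correction. Without extravasated_2, 0 motility genes rose and 2 fell, without extravasated_1, 2 and 3, without not_extravasated_1, 14 and 7, and without not_extravasated_2, 6 and 11. These 4 lists had the same counts adjusted over the list alone, and camera called none of the 3 it tested (adjusted p = 0.485 for integrins, 0.243 for cell-cell adhesion and 0.485 for motility; all 0.866 with an estimated correlation).

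**Figure D3:**
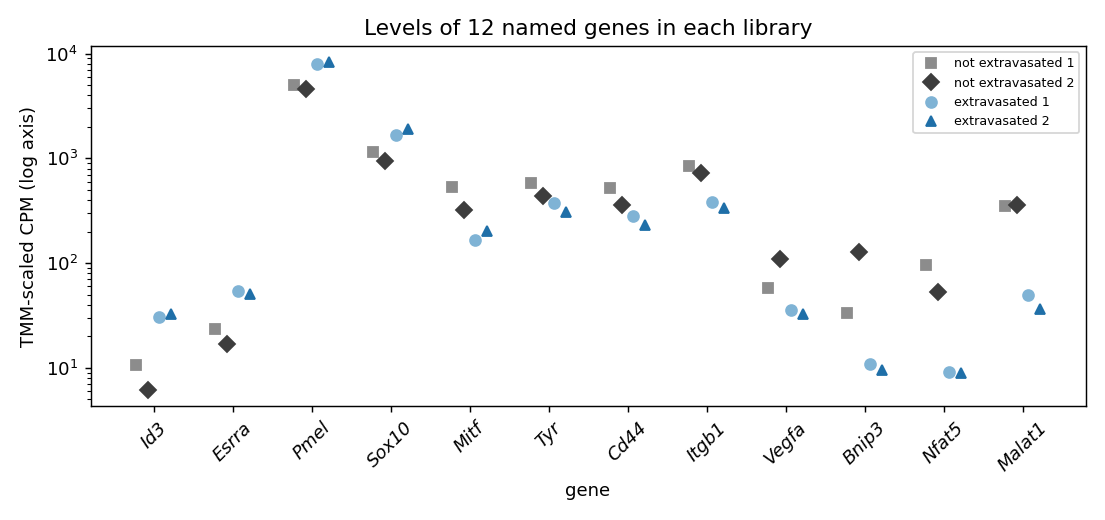
TMM-scaled CPM (log axis) of 12 named genes in each of the 4 libraries; each mark is 1 library. Malat1 and Nfat5 lie lower and Id3 higher in both extravasated libraries, and Bnip3 was 33.3 and 127.9 CPM in the non-extravasated libraries.

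The other lists were not called by camera before correction. Members rose and fell as follows: invasive melanoma state 1 and 1 of 12, mesenchymal 0 and 3 of 14, extracellular matrix 4 and 3 of 24, matrix proteases and inhibitors 4 and 7 of 25, and angiogenic factors 3 and 3 of 17. Antigen presentation by MHC class I had 1 and 4 of 15, chemokines and NF-kB 2 and 2 of 15, and glycolysis 7 and 2 of 22. The glycolysis list held 21 genes, so at least 1 symbol matched more than 1 tested entry. Cholesterol synthesis had 0 and 7 of 25, and fatty acid synthesis 2 and 6 of 16. The integrated stress and unfolded protein list had 6 and 10 of 34, p53 targets 2 and 4 of 21, immediate early genes 3 and 3 of 29, and Notch, Wnt and hedgehog genes 0 and 2 of 15. NRF2 targets had 8 and 4 of 26, and heat shock genes 3 and 8 of 18. Adjusted over the list alone, the counts differed for extracellular matrix (0 and 1), proteases (6 and 7), angiogenic factors (2 and 2), MHC class I (1 and 3), chemokines (0 and 0), cholesterol synthesis (0 and 6), p53 targets (1 and 4), immediate early genes (2 and 2) and the Notch list (0 and 0). Over the 316 tested members of these 16 lists 46 rose and 67 fell. Without extravasated_2 this was 3 and 21, without extravasated_1 19 and 35, without not_extravasated_1 75 and 108, without not_extravasated_2 66 and 80, and after correction 11 and 14. After correction MHC class I and cholesterol synthesis were called lower (both adjusted p = 0.031; 0.80 and 0.82 with an estimated correlation), with 1 and 0 members fallen. With the longest transcript the integrated stress and unfolded protein list was also called lower (median -0.11, adjusted p = 0.0389; adjusted p = 0.855 with an estimated correlation), against an adjusted p of 0.0539 with the principal one. The corrected MHC class I call ended without not_extravasated_1 or extravasated_2, with medians of -0.36 and -0.34, against -0.45 with all libraries. The corrected cholesterol call ended without extravasated_2, with a median of -0.4, and without not_extravasated_2, with a median of 0.08, against -0.39 with all libraries. Hmgcs1, an enzyme of cholesterol synthesis, stood at 130.9 and 229.7 CPM in the non-extravasated libraries and at 48.8 and 37.0 CPM in the extravasated ones. Hsp90b1, a chaperone of the endoplasmic reticulum, fell with a log2 fold change of -1.67, and -0.82 after correction. Cholesterol and fatty acid synthesis were called lower without not_extravasated_1 (adjusted p = 7.87e-05 and 0.0248; both adjusted p = 0.82 with an estimated correlation). Without not_extravasated_2 neither was called, with medians of 0.07 (adjusted p = 0.713) and -0.15 (adjusted p = 0.895). The cholesterol list's median deviation was 0.69 in not_extravasated_2 and -0.28 in not_extravasated_1, and that of fatty acid synthesis 0.46 and -0.10. Without not_extravasated_2, NRF2 targets were called higher and p53 targets lower (both adjusted p = 0.0405; both adjusted p = 0.843 with an estimated correlation). The p53 list's median deviation was 0.55 in not_extravasated_1 and -0.37 in not_extravasated_2.

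The markers of other cell types are mouse genes, so they cannot be used to judge cells of the zebrafish host. The 18 leukocyte markers summed to 7.18 and 6.69 CPM in the non-extravasated and 7.85 and 6.56 CPM in the extravasated libraries. Fibroblast markers summed to 20.7 to 29.4 CPM, with 1 of 5 tested members up and 2 down, and were not called. Keratinocyte markers summed to 1.28 to 2.39 CPM and erythroid markers to 34.7 to 58.5 CPM. Endothelial markers summed to 333.1 and 215.8 CPM against 441.6 and 439.2 CPM in extravasated libraries, most of it from Eng at 326.1 CPM. Of 4 tested endothelial markers 2 rose (4 adjusted over the list alone): Plvap (1.02) and Vwf (1.30), of which Vwf kept its call after correction (1.35). The uncorrected Vwf value was 2.09 without not_extravasated_1 and 0.75 without not_extravasated_2, and 1.36 and 1.24 without extravasated_1 or extravasated_2, where it was not called (adjusted p = 0.134 and 0.20). Y-linked genes had 1 count in all libraries together.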

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

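The GC and length correction with either transcript, GC correction alone and library totals were chosen after the data were seen. The counts of changed, higher and lower genes stayed within 1.5-fold under RLE and upper quartile factors, DESeq2, limma-voom, both other filters, no robust moderation, the title suffix term and library totals (5135 to 6165 changed). A test against a fold of 1.5 called 1719 (156 higher, 1563 lower), and an adjusted p under 0.01 called 2792 (903 and 1889), both by their construction. GC and length correction called 1705 (1005 and 700), with the longest transcript 1665 (995 and 670), and GC correction alone 2157 (1184 and 973). Leaving out 1 library gave 1677 to 6185 changed, 292 to 2743 higher and 1385 to 3477 lower; the lowest of each came without extravasated_2. With correction and 1 library left out, 0, 5, 1810 and 2886 were called (without extravasated_2, extravasated_1, not_extravasated_2 and not_extravasated_1). Camera called 6 lists, 0 with an estimated correlation (edgeR log2 CPM, 0 lists at an unadjusted p under 0.05; fry 1), 8 with GC and length correction, 9 with the longest transcript, which added integrated stress and unfolded protein, 11 with GC correction alone, and 4 to 7 with 1 library left out. The extracellular matrix list, not called before, turned to a called fall under GC correction alone (median -0.27; adjusted p = 0.738 with an estimated correlation). Of the 139 named genes, 7 called genes turned sign under GC and length correction, with log2 fold changes of Dnajc3 0.11, Spred1 0.11, Lamp2 0.23, Atp6v1a 0.12, Slc7a11 0.32, Tyr 0.78 and Cd44 0.20. A further 81 lost their call. With the longest transcript the values were 0.0947, 0.103, 0.22, 0.0947, 0.33, 0.75 and 0.17, and Dnaja1 was 0.10. Under GC correction alone, Dnajc3 was 0.0221, Lamp2 0.28, Atp6v1a 0.0924, Tyr 0.60, Cd44 0.0542, Col4a2 -0.0189 and B2m 0.14. The cause of these turns beyond the removed trend was not tested. Leaving out extravasated_2 ended the call of 62 named genes and leaving out extravasated_1 that of 31. The labels give the groups no shared replicate numbers; the kind of title suffix as an additive term gave 6165 changed genes (2632 higher, 3533 lower) and 7 lists. Depth limits genes near the filter's minimum of 10 counts.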

Other observations

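The gene families, the mitochondrial mRNAs and the tests of the GC and length correction and of the mitochondrial gap were chosen after the results had been seen. Of 79 tested ribosomal protein genes 62 rose and 0 fell by edgeR, with a median log2 fold change of 0.56, and 22 rose and 0 fell after GC and length correction (median 0.25). Subunits of the mitochondrial ribosome rose in 38 of 74 cases and fell in 2, and 22 rose and 0 fell after correction (median 0.28). Proteasome subunits rose in 16 of 35 cases and fell in 4, and in 6 and 0 after correction. Whether the trend with coding sequence length that stayed after correction shapes the rises of these families was not tested. Zfp zinc finger genes, which encode DNA-binding proteins, fell in 130 of 316 cases and rose in 18 (median -0.88), and 5 rose and 21 fell after correction (median -0.08). Of 561 long non-coding RNA genes 92 fell and 17 rose, and 23 fell and 12 rose after correction. Of all 12320 tested genes 3196 fell and 2355 rose, and of 12307 after correction 700 fell and 1005 rose. The shares of long non-coding RNA genes that fell or rose were thus below those of all genes. Of 7 tested mitochondrially encoded mRNAs, 1 rose and 0 fell: mt-Nd1, a subunit of complex I, with a log2 fold change of 0.73 (edgeR adjusted p = 0.0184), while the median of the 7 was -0.15.

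GC-poor transcripts were lower in the extravasated libraries, with a rho of 0.745. Breakage that loses long transcripts, as the whole cause of this trend, is argued against by the 2227 shortest coding transcripts. Their rho with GC was 0.62 (bootstrap interval 0.59 to 0.65). That value does not bear on the trend with transcript length (rho -0.379), for which breakage stays open. The mitochondrially encoded mRNAs, at 34.1 to 39.9% GC, lay 0.85 (0.64 to 1.63) above nuclear coding transcripts of like GC and length. Only 5 of the 7 had enough such transcripts. A difference in the level of mitochondrial RNA would give such a gap under a full GC bias too. Mitochondrial genes took 8.21% and 7.12% of counts in the non-extravasated and 6.51% and 8.88% in the extravasated libraries. The gap therefore cannot decide on a fragment GC bias acting alike on all transcripts. Within those mRNAs the slope per percent GC was 0.0148 (-0.20 to 0.23), which decides nothing, and less recovery of nuclear RNA stays open, since long non-coding RNAs lay -0.25 (-0.31 to -0.19) from coding transcripts of like GC and length, between the bounds set. A fragment GC bias, whether or not it spares the mitochondrial mRNAs, and a difference in RNA handling between the groups stay open. These and a biological shift tied to extravasation cannot be told apart here, because the title number follows the group.

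The hypoxia list was lower in extravasated libraries, with a median log2 fold change of -0.87. The GC and length trend as its whole cause is argued against by a corrected median of -0.86 (bootstrap interval -1.0 to -0.58). Without not_extravasated_2 the median was -0.30 (-0.84 to -0.07), at the bound that would mark the state of that library as the source. After correction it was -0.21, past that bound. The corrected list was still called without that library by camera with the preset correlation. An estimated correlation was not tried in that fit. With all libraries the corrected list had a camera adjusted p of 0.80 with an estimated correlation. The state of that library, or of a culture of its own if it had 1, and a difference tied to extravasation cannot be told apart with 2 libraries per group.

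The interferon list was lower in extravasated libraries, with a median of -0.65. Mouse leukocytes in the non-extravasated cultures are argued against by summed leukocyte markers of at most 7.18 CPM there. In extravasated libraries the sum was up to 7.85 CPM. These markers are mouse genes, so they cannot decide on leukocytes of the zebrafish host. The corrected median of -0.58 (-0.62 to -0.35) leaves part of the fall open to the GC and length trend. Without not_extravasated_1 the median was -0.33 (-0.87 to 0.19), and -0.02 after correction, so the state of that library may account for much of the difference, and a difference tied to extravasation cannot be told apart from it with 2 libraries per group.

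Over 11514 windows of 40 neighbouring tested genes, the largest median of corrected log2 fold change was 0.37 in size (chromosome 9, 70542754 to 77794485, lower), under the highest of 100 shuffles of gene order (0.43). Over genes above 5 CPM alone, a filter tried before that test was run as written, the largest was 0.42 against 0.39, with 3 of 8931 windows beyond the highest shuffle.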
